A study of Mus musculus with 6 samples.

How the data were processed

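ATAC-seq libraries of mouse CD4 T cells were analysed: 2 of low dose Tfh cells, 2 of high dose Tfh cells and 2 of naive cells. The labels state that Tfh cells were sorted by PD-1, CXCR5, CD44 and CD4, without FOXP3, Ly6C or CD162, and naive cells by CD4 with low CD44 and no FOXP3, among other markers. Libraries were made with an Illumina Nextera kit per the labels. The deposited table holds raw fragment counts per consensus peak, made by the authors with featureCounts 2.0.1 in paired mode, allowing overlaps, with at least 0.2 of a fragment inside the peak, per the file headers. Peaks came from MACS2 on build GRCm38 per the labels, and the aligner is not given in the sources used here. The deposited annotation, made with HOMER, gives for each peak its class and its other value, a signed distance in bp to the nearest annotated TSS, per the file headers. The deposited counts were whole numbers, and their totals ran from 32392426 to 46761032 per library.

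Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr and quasi-likelihood F tests with robust dispersion over all 6 libraries. Benjamini-Hochberg adjusted p-values below 0.05 were called, and every adjusted p of a gene or peak in the text is from edgeR unless another tool is named. The Tfh difference is the mean of both doses minus naive, and the dose difference is high minus low. Of 82463 peaks, 82378 passed the filter, and the biological coefficient of variation was 0.111. Gene-level counts were summed over peaks whose nearest TSS lay within 50 kb, which held 71709 peaks (87.0%) and 23374 genes, of which 23362 passed the filter. CPM is edgeR's cpm, the fragment count scaled by TMM-adjusted library totals. Errors are the SD of 2 libraries for CPM and the standard error for log2 differences.

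The lists were 19 in number: sort gate, Tfh programme, naive and quiescence, type 1, type 2, type 17, regulatory T cell, interferon response, T cell receptor activation, IL-2 and STAT5, migration, cell cycle, T cell core, housekeeping, B cell, myeloid and dendritic, CD8 and NK, stromal and epithelial, and erythroid genes. They held 333 genes, of which 307 had a gene-level value. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and list medians are of log CPM differences unless stated. No list was called with an estimated correlation by camera in either comparison. In that test 1 list of the Tfh difference and 2 of the dose difference had an unadjusted p below 0.05, and fry called 13 and 5 lists. Fry tests whether a list's genes move on balance to the same side, and its mixed form tests change in either direction.

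Comparisons, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, for each main comparison, up to 6 genes with higher and 6 with lower peaks. These had an adjusted p below 0.05, a log2 difference of at least 1 in size and no overlap between the libraries compared, and were ranked by p, with a single peak per protein-coding gene. It also took up to 2 higher and 2 lower genes from each list, by the smallest adjusted p. The sort gate genes, Bcl6, Il21, Tcf7, Tbx21, Ifng, Cxcr3, Gata3, Il4, Il13 and Il10 were always taken, except that 1 sort gate gene is not reported here. Location classes were tested with Fisher's exact test against all tested peaks. Overlap of the doses was set against 5 simulated draws in which no group differed. Replicate libraries had Spearman correlations across peaks of 0.992 in naive, 0.98042 in low dose and 0.979 in high dose cells.

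The method was tested on simulated data with known changes in 100 features at each fold. Between doses it recovered 18% of peaks changed 1.5-fold and 48% changed 2-fold, and 59% and 87% of genes. For the Tfh difference it recovered 25% and 63% of peaks and 72% and 91% of genes. It made 11 false calls in peaks and 11 in genes between doses, and 10 in peaks and 28 in genes for the Tfh difference. Intervals and recovery cover counting error and simulated spread only. The adjustment is stricter when few features change, as in this simulation, so recovery may be higher where many do.

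The alternatives were DESeq2 1.42.0, RLE factors, library totals, loess offsets, other filters, a fold threshold of 1.5, autosomes only, only the groups compared, a replicate block, peaks within 1 or 10 kb, other list tests, a stricter threshold of 0.01 and leaving out each library. A B-cell score or, for lists, a CD8 and NK score as a covariate, thinning to the smallest total, the nearest RefSeq protein-coding gene and a separate naive library as the control of each dose were added after seeing the data. For single genes the covariate is the B-cell score. The B-cell score was 1.50 and 1.53 in naive, 1.86 and 2.06 in low dose and 2.88 and 2.36 in high dose libraries (log2). It parted the groups without overlap, so fits with it rest on gaps between replicates. The CD8 and NK score was 3.23 and 3.24 in naive, 2.85 and 2.81 in low dose and 2.59 and 2.70 in high dose libraries (log2). It followed the groups closely. Fits with it rest on small gaps between replicates, chiefly at high dose, and part it poorly from the groups. Motif searches and GC corrections were not run, since they need a genome sequence that was not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.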

Results

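Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in CD4 T cells from mice labelled as FIR mice. T follicular helper (Tfh) cells, the CD4 T cells that help B cells in germinal centres, came from the mesenteric lymph nodes of mice infected with the whipworm Trichuris muris and taken at day 21. Mice had received 30 eggs (low dose, a chronic infection) or 200 eggs (high dose, an acute infection), and naive CD4 T cells came from uninfected mice. Each of the 3 groups had 2 libraries. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries. Fragments counted in peaks came to 46761032 and 33794513 in the high dose libraries, 35628487 and 32392426 in the low dose libraries, and 41174169 and 41818831 in the naive libraries. The deposited peak set held 82463 peaks with a median width of 494 bp, of which 43.5% lay in introns, 30.3% between genes and 15.7% at promoters. The first principal component carried 85.6% of the variance of log counts and parted naive from Tfh libraries, and the second carried 9.47%.

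The first comparison asks which chromatin regions set Tfh cells of both doses apart from naive CD4 T cells. Chromatin at Cebpa, which encodes a transcription factor best known from myeloid cells and liver, was higher in Tfh cells, with gene-level CPM (fragment counts scaled by library size) of 4.88 ± 0.0203 in naive cells, 96.9 ± 3.82 at low dose and 114 ± 7.41 at high dose (mean ± SD, n = 2 in each group). Maf, a transcription factor of Tfh cells, rose from 54.5 ± 1.95 to 206 ± 3.33 and 240.1 ± 8.94 CPM. Il10, an anti-inflammatory cytokine gene, rose from 17.04 ± 0.302 to 159.7 ± 2.22 and 147.7 ± 17.1 CPM, and Il17a, a cytokine gene of Th17 cells, from 1.07 ± 0.179 to 27.5 ± 3.71 and 21.2 ± 0.709 CPM. Dapl1, a gene of naive T cells, fell from 171 ± 12.1 to 54.4 ± 0.935 and 54.2 ± 5.11 CPM. Of 82378 peaks tested, 29147 were higher and 28500 lower in Tfh cells by edgeR at a Benjamini-Hochberg adjusted p below 0.05. The log2 difference was at least 1 in size at 19023 of the higher and 16902 of the lower peaks. At gene level 15179 of 23362 genes were called, 7732 higher and 7447 lower. With library totals alone as scaling, 9773 genes were higher and 6213 lower, a higher share of 61.1% against 50.9%, and the median of all genes moved from 0.01 to 0.10 on the log2 scale.

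The regions with the smallest p in Tfh against naive cells were low in either Tfh or naive cells (GRCm38 positions). Among higher peaks, the Cebpa promoter (chromosome 7, 35118059 to 35119685) had a log2 difference of 3.93 ± 0.09 (SE). An exonic peak 7762 bp from the TSS of Mmp10, a matrix metalloproteinase gene (chromosome 9, 7509708 to 7510520), differed by 8.31 ± 0.18, with 0.160 CPM in naive cells against 49.6 and 53.6 in low and high dose Tfh cells. A peak in an exon assigned to Ttc39c (chromosome 18, 12642976 to 12644527) differed by 5.56 ± 0.11. Peaks assigned to Atp6v1g2, Dip2b and Glt28d2 were higher by 5.60, 4.58 and 3.80. Among lower peaks, an intergenic region at -10488 bp from the TSS of Cxcr4, a chemokine receptor gene (chromosome 1, 128602358 to 128603204), had a log2 difference of -4.45 ± 0.11, from 43.3 CPM in naive cells to 2.21 and 1.78. A peak at -2270 bp from the TSS of Pik3ip1, an inhibitor of PI3K signalling (chromosome 11, 3328358 to 3328688), differed by -3.70 ± 0.10. Peaks assigned to Cck, P4ha2, Plaur and Tspan9 differed by -2.90, -4.38, -3.47 and -4.64. The 12 peaks had adjusted p-values from 2.5e-14 to 1.6e-13 and kept their calls under every alternative run for them.

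Genes of the Tfh programme rose as a group in Tfh cells. Of 27 measured, 17 rose, 3 fell and 7 were not called (17 and 3 adjusted over the list alone), with a camera adjusted p of 0.000936 and a median log2 difference of 0.51. The test gave an adjusted p = 0.768 with an estimated correlation, and with the CD8 and NK marker score of each library as a covariate the median was -0.10 (camera adjusted p 0.401). Bcl6, the repressor that defines the Tfh lineage, rose by 0.95 ± 0.10 over 5 peaks that were all higher, from 8.53 to 13.3 and 20.5 CPM. When peaks were given to the nearest RefSeq gene instead, Bcl6 was called lower, with a log2 difference of -0.16 (adjusted p 0.00433). The members that fell were Il6st, the shared IL-6 receptor chain (-0.46 ± 0.05), Tox, a factor of T cell development and exhaustion (-0.60 ± 0.06, but -0.020 and not called with nearest RefSeq genes), and Cd40lg, the ligand through which T cells help B cells (-0.29 ± 0.04; Cd40lg was named after its values were seen). Il21, the Tfh cytokine, had no gene-level value under the deposited assignment. Counted over the nearest RefSeq gene, Il21 was at 147 ± 10.8 CPM in naive cells, 219 ± 11.7 at low dose and 190.2 ± 17.8 at high dose, a log2 difference of 0.47 (adjusted p 9.46e-05). The Il21 promoter peak (chromosome 3, 37232522 to 37233175) was at 0.381 ± 0.0266 CPM in naive cells against 25.5 ± 2.93 and 17.7 ± 2.28 in Tfh cells.

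Naive and quiescence genes fell as a group: of 24 measured, 1 rose, 18 fell and 5 were not called (1 and 18 adjusted over the list alone; camera adjusted p 8.18e-07, median -0.71). The adjusted p = 0.325 with an estimated correlation. Dapl1 had a log2 difference of -1.66 ± 0.06 and Pdlim1, a cytoskeletal adaptor gene, of -1.25 ± 0.05. Tcf7, which encodes the factor TCF-1 of naive and memory T cells, fell by 0.53 ± 0.05, with 13 of its 16 peaks lower and 2 higher. Its strongest peak lay between genes (chromosome 11, 52309498 to 52309884) and went from 32.6 CPM to 8.97 and 9.56. Igf1r, a growth factor receptor, was the member that rose (0.48 ± 0.05), but with nearest RefSeq genes it was called lower (-0.57, adjusted p 1.83e-07). Genes of the T cell receptor complex and its signalling core fell together, with 12 of 14 lower and 2 not called (12 lower adjusted over the list alone). Their camera adjusted p was 0.00195 with a median of -0.33, and the adjusted p = 0.325 with an estimated correlation. Cd3e, a chain of the receptor complex, differed by -0.61 ± 0.04 and Lck, its proximal kinase, by -0.64 ± 0.05 (-0.079 and not called with nearest RefSeq genes).

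The sort gate genes encode the proteins used to sort the cells. For those gated differently in Tfh and naive cells the direction is not independent evidence. Both kinds of cell were sorted with CD4 and without FOXP3, so the gate does not set the direction of Cd4 or Foxp3. Of 9 measured, 1 rose, 7 fell and 1 was not called (2 rose and 7 fell adjusted over the list alone; camera adjusted p 0.0111, median -0.99, adjusted p = 0.700 with an estimated correlation). The list was not called with nearest RefSeq genes (camera adjusted p 0.0620) or over peaks within 1 kb of the TSS, where its median was 0.49. Pdcd1, the receptor PD-1, rose by 0.40 ± 0.06, with 9 of 11 peaks higher, and was at 0.091 ± 0.10 and not called with the B-cell marker score of each library as a covariate. Its intronic peak on chromosome 1 (94042061 to 94043010) went from 0.710 CPM to 10.2 and 15.4. Cxcr5, the follicular homing receptor, was not called (0.22 ± 0.10, adjusted p 0.0674, and 0.31 and called without high dose replicate 2), although 10 of its 13 peaks were higher and 1 lower. Its peak of smallest p (chromosome 9, 44528390 to 44528549) differed by 3.12 ± 0.22. Selplg, which encodes CD162, differed by -1.12 ± 0.04, Ly6c1 by -2.48 ± 0.11, Ly6c2 by -0.99 ± 0.08, Foxp3 by -1.69 ± 0.12 and Cd4 by -0.42 ± 0.05 (-0.13 and not called within 1 kb of its TSS). Cd44, an activation marker carried at a high level by the sorted Tfh cells, differed by -0.39 ± 0.05 over 5 peaks, of which 3 were higher and 2 lower. Over peaks within 1 kb of its TSS it was higher by 0.49, and with nearest RefSeq genes its value was 0.17.

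Among the remaining gate genes and fixed regulators, the peak of smallest p in Tfh against naive cells was lower at Cd44 (chromosome 2, 102909243 to 102909968, log2 difference -2.22 ± 0.13) and Cd4 (chromosome 6, 124891534 to 124891682, -2.68 ± 0.25). It was also lower at Selplg (chromosome 5, 113824256 to 113824850, -1.48 ± 0.10), Foxp3 (X chromosome, 7587453 to 7587936, -2.41 ± 0.18), Ly6c1 (chromosome 15, 75052041 to 75053041, -2.40 ± 0.12), Ly6c2 (chromosome 15, 75117381 to 75117981, -0.81 ± 0.10) and Gata3 (chromosome 2, 9871002 to 9871993, -0.87 ± 0.10). It was higher at Bcl6 (chromosome 16, 23962364 to 23963411, 0.76 ± 0.12), Ifng (chromosome 10, 118435195 to 118436043, 5.77 ± 0.23), Cxcr3 (X chromosome, 101737045 to 101737833, 4.81 ± 0.24) and Il10 (chromosome 1, 130993459 to 130994245, 3.16 ± 0.08). At chromosome 11 it was higher at Il4 (53609371 to 53610343, 4.38 ± 0.20) and Il13 (53626711 to 53627501, 5.38 ± 0.34). The intronic Tbx21 peak (chromosome 11, 97109077 to 97109348) was at 0.0245 CPM in naive cells against 6.54 ± 0.104 at low dose and 2.25 ± 0.00719 at high dose.

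Genes of the other helper lineages went both ways in Tfh against naive cells. Of 24 type 1 genes, 11 rose, 8 fell and 5 were not called (camera adjusted p 0.866). Cxcr3, a chemokine receptor of Th1 cells, rose by 2.13 ± 0.11, Tbx21, the Th1 master factor T-bet, by 1.56 ± 0.09, Bhlhe40, a cytokine regulator, by 1.86 ± 0.06 and Ifng by 0.46 ± 0.08. Ifng was at 3.57 over peaks within 10 kb of its TSS and at 0.097 ± 0.13 and not called with the B-cell score as a covariate. Stat4, which relays IL-12 signals, differed by -1.35 ± 0.08 (0.15 and called higher with nearest RefSeq genes), and Gzmb, granzyme B, by -0.91 ± 0.05. Of 19 type 2 genes, 12 rose, 6 fell and 1 was not called (camera adjusted p 0.168). Il10 rose by 3.17 ± 0.08 with 12 of 12 peaks higher, Il4 by 3.29 ± 0.22, Il13 by 1.56 ± 0.13 and Areg, an epithelial growth factor, by 2.95 ± 0.17. Gata3, the Th2 master factor, differed by -0.41 ± 0.05, Il4ra, the IL-4 receptor, by -0.63 ± 0.04 and the chemokine receptor gene Ccr8 by -1.03 ± 0.07. Over peaks within 1 kb of the TSS these 3 genes were not called (-0.11, -0.048 and -0.10). Of 13 type 17 genes, 7 rose, 3 fell and 3 were not called (camera adjusted p 0.168), with Il17a at 4.49 ± 0.15 and the IL-1 receptor gene Il1r1 at 2.31 ± 0.13, and Il17re at -1.60 ± 0.17. Of 13 regulatory T cell genes, 4 rose, 6 fell and 3 were not called (camera adjusted p 0.737, tested downward, with a median of -0.12 and a mean of 0.06). Cd83 rose by 1.94 ± 0.10 and Ikzf4, which encodes Eos, differed by -0.996 ± 0.05. Adjusted over the list alone these 4 lists gave the same counts.

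Response lists went both ways in Tfh against naive cells, and none was called without a covariate. Of 22 interferon response genes, 6 rose, 10 fell and 6 were not called (6 and 11 adjusted over the list alone; camera adjusted p 0.605). Mx1, an antiviral GTPase, rose by 1.57 ± 0.11 and Ifit3 differed by -0.84 ± 0.10. Of 20 T cell receptor activation genes, 5 rose and 7 fell (camera adjusted p 0.877, tested downward with a median and mean above 0), with the inhibitory receptor Lag3 at 0.49 ± 0.05 and the AP-1 gene Jun at -0.45 ± 0.04. Of 13 IL-2 and STAT5 genes, 4 rose and 4 fell (camera adjusted p 0.737). Il2rb, the IL-2 receptor beta chain, rose by 1.49 ± 0.05 and Prdm1, which encodes Blimp-1, differed by -0.54 ± 0.05. Of 15 migration genes, 4 rose and 5 fell (camera adjusted p 0.854, tested downward with a mean below 0 and a median above it, and 0.00778 with the CD8 and NK score as a covariate), with the gut homing receptor Gpr15 at 2.04 ± 0.10 (-1.0015 over peaks within 1 kb of its TSS, and 0.099 and not called within 10 kb) and Ccr2 at -1.53 ± 0.08. Of 17 cell cycle genes, 10 rose and 2 fell (camera adjusted p 0.322), with cyclin A2, Ccna2, at 0.38 ± 0.05 and cyclin B1, Ccnb1, at -0.43 ± 0.05 (0.06 with nearest RefSeq genes, 0.074 within 1 kb and 0.042 within 10 kb of its TSS). Of 18 housekeeping genes, 4 rose and 4 fell (camera adjusted p 0.984, tested upward with a median of 0.04 and a mean of -0.01), with the tubulin gene Tubb5 at 0.27 ± 0.05 (0.18 and not called within 1 kb of its TSS) and Actb at -0.36 ± 0.04. Adjusted over the list alone the last 5 of these lists gave the same counts.

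Markers of other cells were measured beside these lists. Of 16 B-cell genes, 12 rose and 4 were not called in Tfh cells (12 higher adjusted over the list alone; camera adjusted p 0.00239, median 1.59, adjusted p = 0.800 with an estimated correlation). Cd22, an inhibitory receptor of B cells, rose by 2.95 ± 0.21, from 0.827 CPM to 5.16 and 7.99, and Pax5, the B-lineage factor, went from 0.0372 CPM to 2.80 and 2.51. With the CD8 and NK score as a covariate the B-cell list median was -1.49 (camera adjusted p 0.00511), and the CD8 and NK list was not called. That score followed the groups closely, so the B-cell value rests on small gaps between replicates. Without high dose replicate 1 the median of the list was 1.39. Of 11 CD8 and NK genes, 1 rose and 9 fell (1 and 9 adjusted over the list alone; camera adjusted p 0.00195, median -1.87, adjusted p = 0.325 with an estimated correlation). Cd8b1, a CD8 chain, differed by -2.54 ± 0.08 and Prf1, perforin, by -3.02 ± 0.08, whereas Gzmk, granzyme K, rose by 4.71 ± 0.13. Of 15 myeloid and dendritic genes, 7 rose and 5 fell (camera adjusted p 0.737), with the dendritic factor Zbtb46 at 2.201 ± 0.10 and the integrin Itgam at -2.68 ± 0.10. Of 11 stromal and epithelial genes, 4 rose and 5 fell (camera adjusted p 0.737, tested downward with a median of -0.04 and a mean of 0.17), and Pecam1 differed by -1.01 ± 0.04. Of 6 erythroid genes, 3 rose and 3 fell (camera adjusted p 0.872), with Gata1 at -2.25 ± 0.17. Adjusted over the list alone these last 3 lists gave the same counts.

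**Figure D1:**
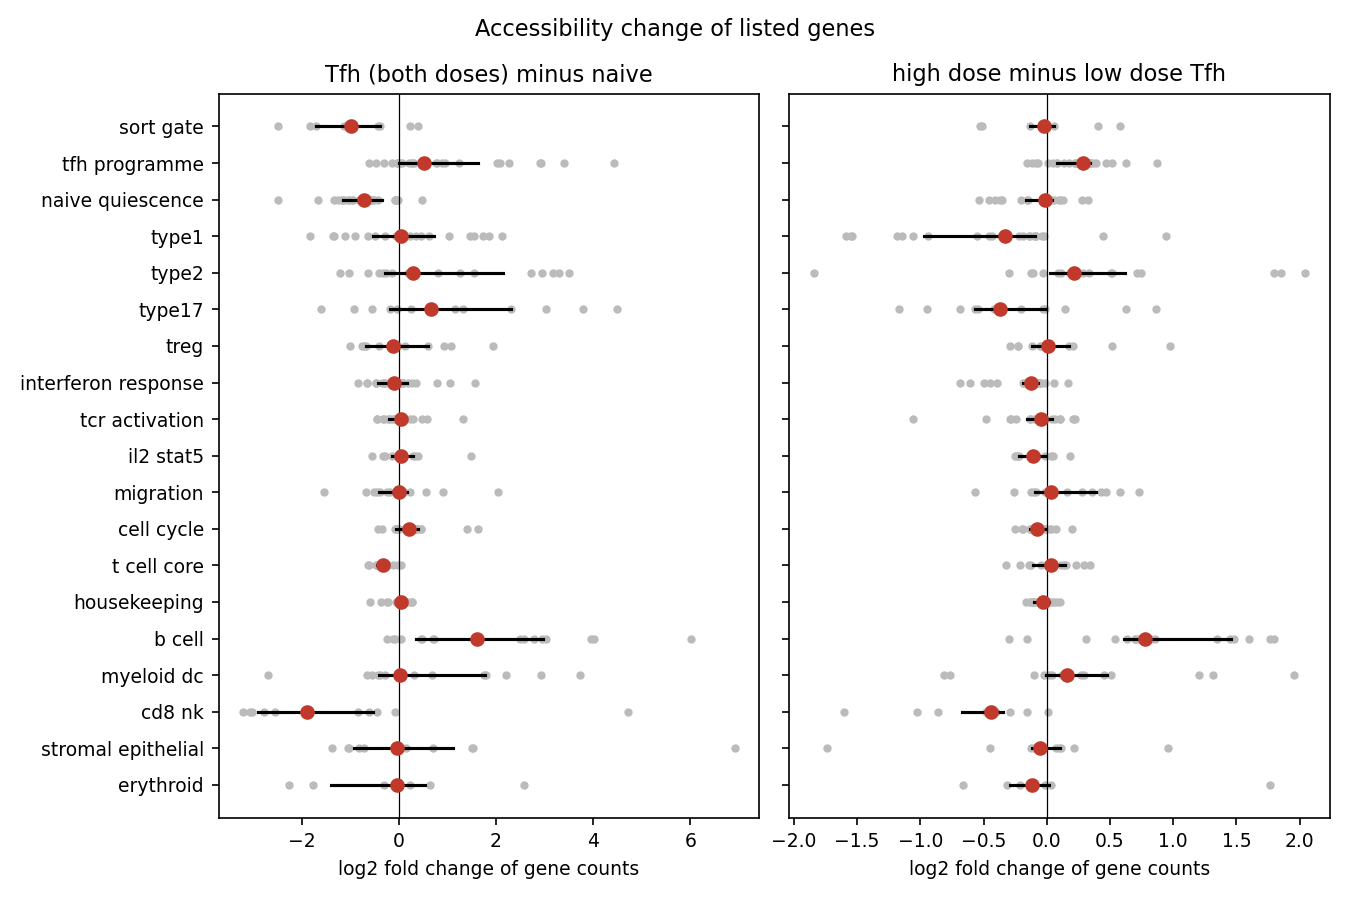
Log2 difference of gene counts for every member of the 19 lists, Tfh minus naive on the left and high minus low dose on the right. Grey points are genes, red points the list medians and black bars the interquartile ranges; between doses the type 1 median was -0.33 and the B-cell median 0.77, both of edgeR fitted values.

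The second comparison asks how Tfh cells of the acute, high dose infection differ from those of the chronic, low dose infection. Chromatin at the type 2 cytokine genes Il4 and Il13 was higher at high dose. Il4, the main type 2 and B-cell help cytokine, went from 24.6 ± 9.13 to 101 ± 3.81 CPM and Il13 from 8.58 ± 1.08 to 29.9 ± 3.44 CPM (mean ± SD, n = 2 in each group). In naive cells Il4 was at 5.08 ± 0.0543 and Il13 at 5.43 ± 0.487 CPM. Il5, named after its values were seen, had no gene-level value under the deposited assignment. Over the nearest RefSeq gene it was at 31.4 ± 1.16 CPM at low dose and 30.9 ± 0.121 at high dose (log2 difference -0.019 ± 0.07, adjusted p 0.891). No tested peak lay within Il5, so this value comes from peaks outside the gene. It cannot show whether chromatin at Il5 itself differed. Chromatin at type 1 genes was lower at high dose: Tbx21 went from 63.5 ± 9.21 to 28.7 ± 1.13 CPM, Cxcr3 from 36.6 ± 0.133 to 17.5 ± 2.75, and Ccl5, a chemokine of effector cells, from 33.5 ± 0.269 to 11.5 ± 0.205. Of 82378 peaks, 10821 were higher and 6342 lower at high dose by edgeR, 6158 and 2765 of them by a log2 difference of at least 1. At gene level 3769 genes were called, 2371 higher and 1398 lower. With loess scaling 8338 peaks were higher and 7468 lower, a higher share of 52.8% against 63.0%, and DESeq2 called 10941 peaks. Without high dose replicate 1, 7582 peaks (3747 higher, 3835 lower) and 2022 genes were called, and without low dose replicate 1, 7303 peaks and 1060 genes. With the B-cell score as a covariate, 236 peaks (120 higher, 116 lower) and 66 genes (15 higher, 51 lower) were called, a higher share of 22.7% of genes. Of 57 called genes that the rule named for this comparison, 8 kept the call with the covariate: Il13, Il12rb2, Ccl5, Cxcr3, Ifng, Ly6c2, Pdlim1 and Itgax.

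Type 2 genes rose as a group at high dose: of 19 measured, 10 rose, 1 fell and 8 were not called (11 and 2 adjusted over the list alone; camera adjusted p 0.000519, median 0.22). The adjusted p = 0.441 with an estimated correlation. The list was also not called over peaks within 1 kb of the TSS (camera adjusted p 0.0534) or with the CD8 and NK marker score as a covariate (median 0.08, 0.0556). It held Rad50 and Kif3a, which are neighbours of the cytokine genes. Il4, Il13, Rad50 and Kif3a were all among the genes that rose and lie at a single locus. They are therefore not independent members of the list. Il4 rose by 2.04 ± 0.20 (adjusted p 0.00116), Il13 by 1.80 ± 0.13 (adjusted p 0.000157) and Ccr4, a chemokine receptor of Th2 cells, by 0.52 ± 0.05. With the B-cell score as a covariate Il4 was at 1.72 ± 0.39 and not called (adjusted p 0.246). In that fit Gata3 (0.25 ± 0.10) and Ccr4 (0.41) were not called either, and Il13 was at 1.99 ± 0.23 (adjusted p 0.0135). Gata3 rose by 0.29 ± 0.05 and was not called without low dose replicate 1 (0.24, adjusted p 0.0651). Its promoter peak (chromosome 2, 9875860 to 9876518) was higher by 0.53 ± 0.09. Il1rl1, the IL-33 receptor, was the member that fell (-1.84 ± 0.20, and -1.53 and not called with the covariate), from 35.3 ± 11.6 to 9.85 ± 0.215 CPM. Il10 was not called (-0.11, adjusted p 0.324; -0.25 and called without high dose replicate 1), and its peak of smallest p (chromosome 1, 131025869 to 131026158) differed by -1.26 ± 0.23. Mean CPM per peak of the type 2 list was 13.97 and 13.6 in the high dose libraries and 11.8 and 11.9 in the low dose libraries. That of the B-cell list was 7.35 and 5.12 at high dose and 3.63 and 4.17 at low dose. Without high dose replicate 1 the type 2 median was 0.16 (camera adjusted p 0.00243).

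Across the type 2 cytokine locus from Kif3a to Il5 on chromosome 11, 13 of 16 peaks were higher at high dose and the rest were not called. None of these peaks lay within Il5. Il4 had 4 of 4 peaks higher. The peak of smallest p lay at its promoter (53618356 to 53619198), at 2.09 ± 0.896 CPM at low dose and 13.3 ± 1.02 at high dose, a log2 difference of 2.68 ± 0.24. A peak assigned to Il4 by nearest TSS, at 53605127 to 53606294, went from 9.84 ± 4.41 to 42.9 ± 1.51 CPM. It was annotated as intronic but lay outside the RefSeq span of Il4 (53612460 to 53618665). Il13 had 3 of 3 peaks higher, of which the strongest, between genes at 53626711 to 53627501, went from 1.75 ± 0.562 to 13.0 ± 2.21 CPM. Higher peaks also lay in an intron of Kif3a (53590349 to 53591108, log2 difference 1.17 ± 0.11) and in an intron by Rad50 (53671299 to 53671734, 1.84 ± 0.37). These single peaks of Kif3a and Rad50, and the peak at 53605127 assigned to Il4, were singled out after their values were seen. Kif3a and Rad50 are themselves in the type 2 list, so these peaks are part of its rise.

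**Figure D2:**
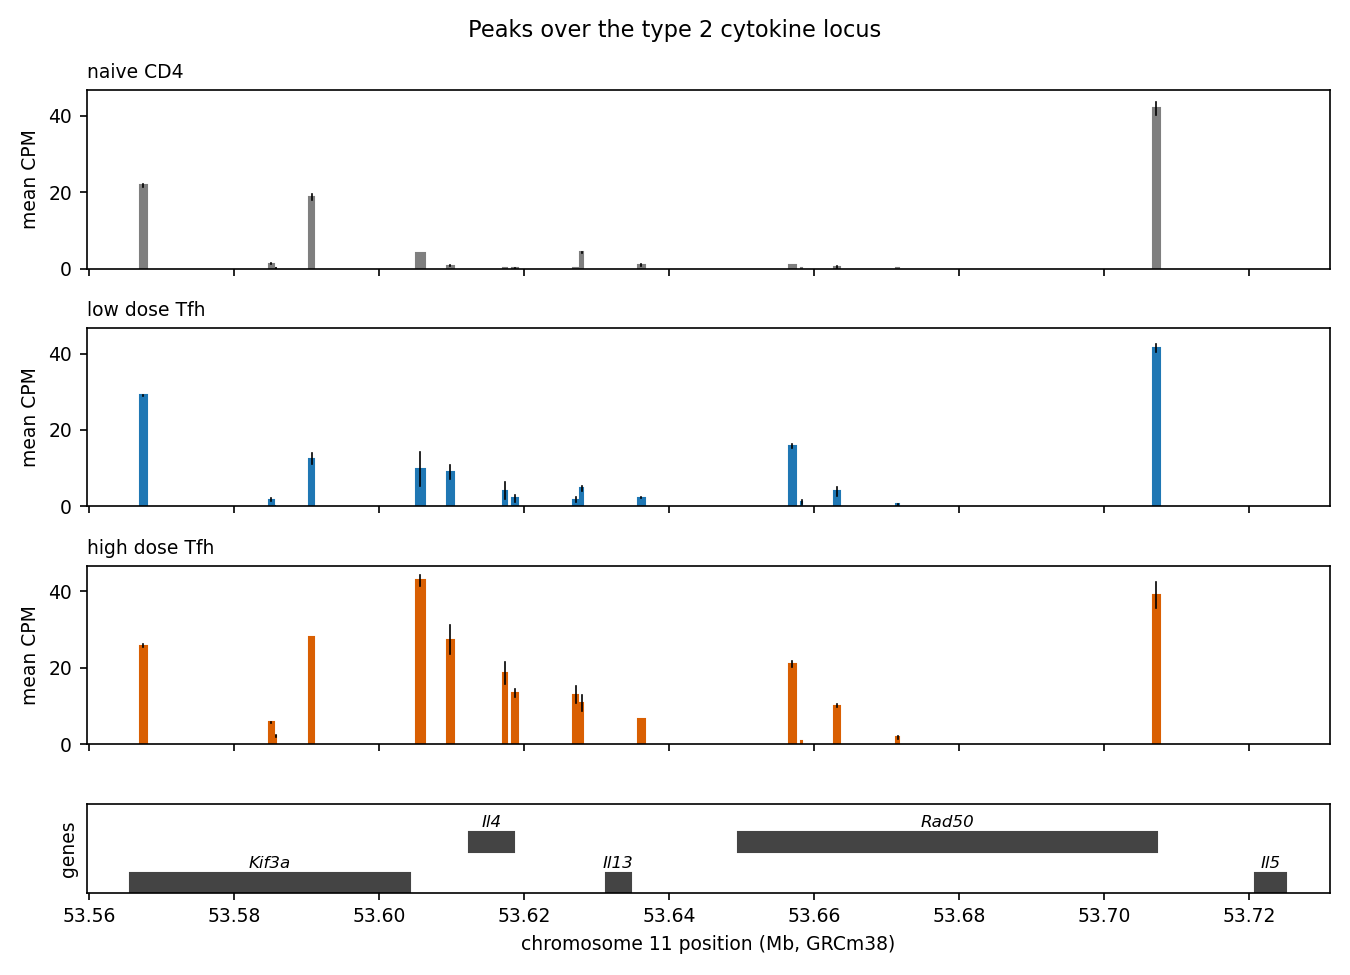
Peaks over the type 2 cytokine locus on chromosome 11, with position in Mb (GRCm38) on the x axis and mean CPM of each group on the y axis; bars span each peak, lines show 1 SD (n = 2) and the lowest panel shows the genes. The peak at 53605127, assigned to Il4 by nearest TSS but outside the gene as drawn, reached 42.9 CPM at high dose against 9.84 at low dose.

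Type 1 genes fell as a group at high dose: of 24 measured, 2 rose, 13 fell and 9 were not called (2 and 14 adjusted over the list alone; camera adjusted p 8.26e-10, median -0.33). The adjusted p = 0.10032 with an estimated correlation. Il12rb2, a chain of the IL-12 receptor, fell by 0.94 ± 0.05 (adjusted p 4.57e-05), Ccl5 by 1.54 ± 0.10 (adjusted p 6.18e-05), Tbx21 by 1.14 ± 0.10 (adjusted p 0.000353) and Cxcr3 by 1.06 ± 0.11. With the B-cell score as a covariate Tbx21 was at -1.09 ± 0.20 and not called (adjusted p 0.0670), and within 1 kb of its TSS it was at -0.64 and called. Tbx21 had 4 of 4 peaks lower, the strongest in its intron (chromosome 11, 97112520 to 97113133), from 16.4 ± 3.73 to 3.86 ± 0.677 CPM. Cxcr3 had 4 of 5 peaks lower, the strongest at -3170 bp from its TSS (X chromosome, 101737045 to 101737833), from 16.3 to 4.98 CPM. Ifng, the main type 1 cytokine gene, fell by 0.43 ± 0.09 with 10 of 19 peaks lower and 2 higher. Its gene-level call was lost without low dose replicate 1 (-0.40, adjusted p 0.142) and without low dose replicate 2 (-0.46, adjusted p 0.0547), and with nearest RefSeq genes (-0.39, adjusted p 0.0509). It was at -2.01 over peaks within 1 kb of its TSS. The members that rose were Cxcr6 (0.45 ± 0.09) and Xcl1 (0.95 ± 0.21), a chemokine receptor and a chemokine. They were at 0.34 and 0.82 and not called without low dose replicate 1, and Cxcr6 was at 0.34 and not called without high dose replicate 1. With the covariate neither was called (0.17 and 1.21), and Xcl1 was at 0.13 and not called with nearest RefSeq genes. Mean CPM per peak of the type 1 list was 9.64 and 9.50 at high dose and 11.9 and 11.7 at low dose, and its median without high dose replicate 1 was -0.34. Markers of CD8 and NK cells fell as well (list median -0.43). Of the type 1 genes that fell, Ccl5, Nkg7 (-1.55) and Ccl4 (-1.59) are also active in those cells, and the last 2 were named after their values were seen.

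**Figure D3:**
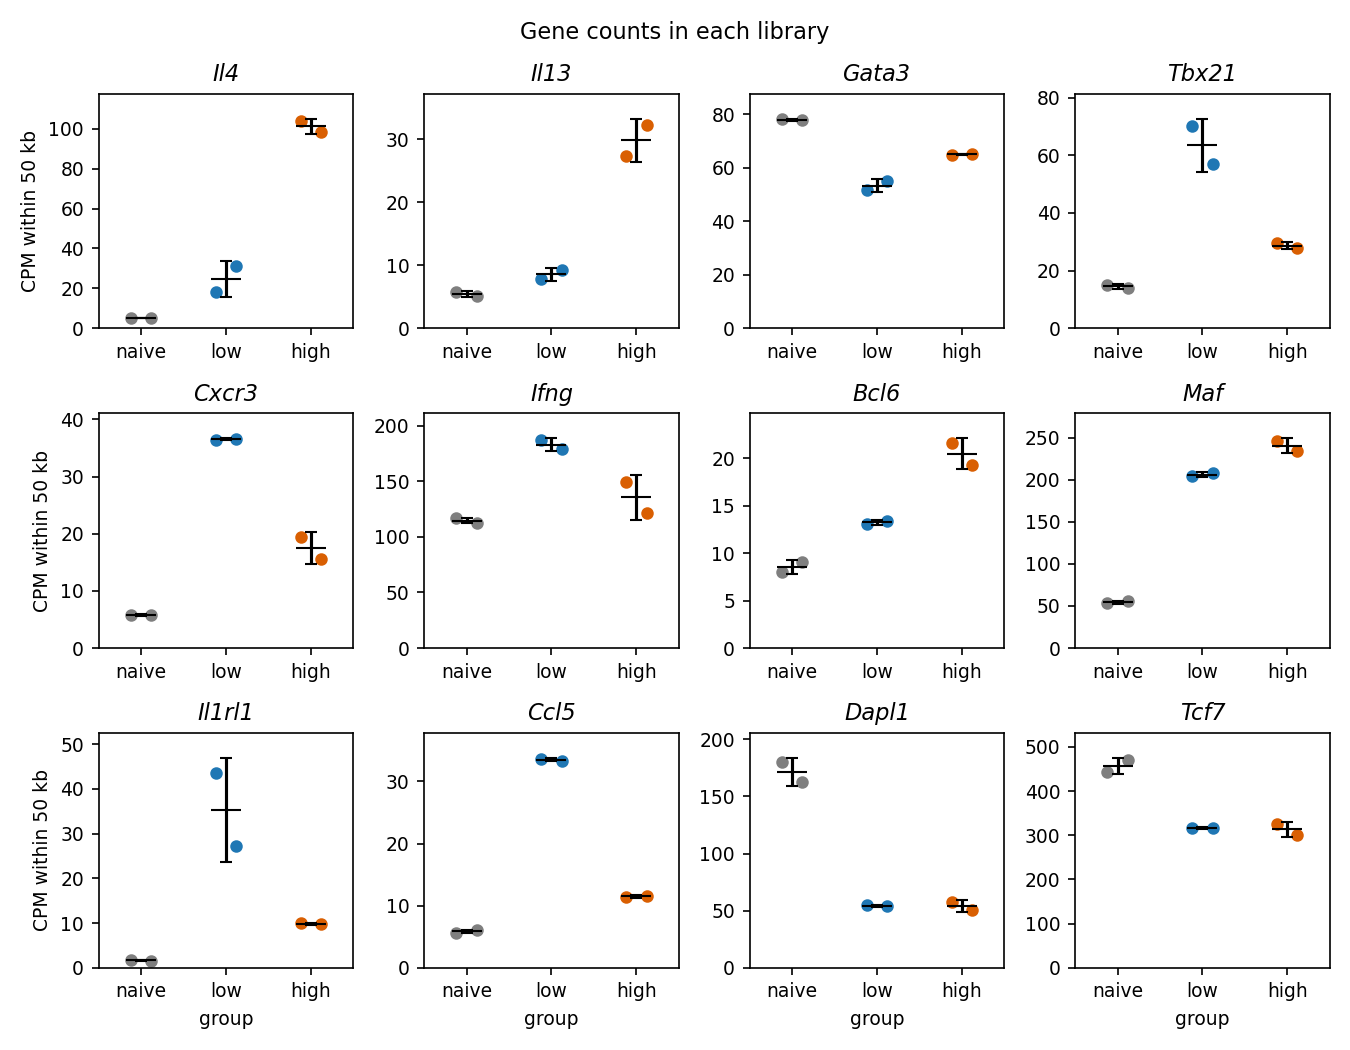
CPM summed over peaks within 50 kb for 12 genes, by group on the x axis; points are libraries, horizontal lines means and bars 1 SD (n = 2). Il4 stood at 101 CPM at high dose against 24.6 at low dose, and Tbx21 at 28.7 against 63.5.

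Tfh programme genes rose as a group at high dose: of 27 measured, 15 rose and 12 were not called (18 and 1 adjusted over the list alone; camera adjusted p 6.38e-06, median 0.29). The adjusted p = 0.512 with an estimated correlation. The list was also not called by fry (adjusted p 0.0771) or with the B-cell or the CD8 and NK score as a covariate (medians 0.12 and 0.10, camera adjusted p 0.207 and 0.688). Ascl2, a factor that promotes CXCR5 and follicular migration, rose by 0.87 ± 0.10 from 27.4 ± 1.58 to 49.9 ± 5.75 CPM, Bcl6 by 0.63 ± 0.11 (adjusted p 0.00547), and Cd40lg by 0.33 ± 0.05. With the B-cell score as a covariate none of these 3 genes was called (0.56 ± 0.15, 0.42 ± 0.21 and 0.25 ± 0.09). Cd40lg and Tox, both among the members that rose, were lower in Tfh than in naive cells. Bcl6 was at 0.13 and not called with nearest RefSeq genes, and Cd40lg was not called with nearest RefSeq genes (0.20) or over peaks within 1 kb (0.19) or 10 kb (0.18) of its TSS. Bcl6 had 3 of 5 peaks higher, the strongest at chromosome 16, 23962364 to 23963411 (0.49 ± 0.13). Il21 was not called (-0.20 with nearest RefSeq genes, adjusted p 0.104), and its peak at chromosome 3, 37257576 to 37258233 differed by -1.38 ± 0.15. The Il21 promoter peak was also lower (-0.52 ± 0.13, adjusted p 0.00849), as were other Il21 peaks, and none was called higher. All 15 genes that rose stood higher in high dose replicate 1 than in replicate 2. The list mean was 14.8 and 13.8 CPM per peak in the high dose libraries and 12.3 and 12.7 in the low dose libraries. Its median without high dose replicate 1 was 0.17 (camera adjusted p 0.000506), and the B-cell median went from 0.72 to 0.43 (camera adjusted p 5.79e-05).

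B-cell genes rose at high dose: of 16 measured, 12 rose and 4 were not called (14 higher and 1 lower adjusted over the list alone; camera adjusted p 5.37e-06, adjusted p = 0.512 with an estimated correlation and 0.147 by fry). With the CD8 and NK score as a covariate the list was not called and its median was -0.21 (camera adjusted p 0.142). Fcer2a, the low-affinity IgE receptor CD23, rose by 1.60 ± 0.23, from 2.35 CPM at low dose to 8.75 and 5.37 in high dose replicates 1 and 2. Cd79b, a B-cell receptor chain, rose by 0.85 ± 0.15, from 25.9 CPM to 54.2 and 39.1, and was not called without low dose replicate 1 (0.72, adjusted p 0.113). CD8 and NK genes fell: of 11, 5 fell and 6 were not called (5 lower adjusted over the list alone; camera adjusted p 1.16e-05, median -0.43, adjusted p = 0.233 with an estimated correlation). Gzmk differed by -1.03 ± 0.10 and Klrc1, an inhibitory NK receptor, by -1.61 ± 0.17, and Prf1 (-0.86), Cd8b1 (-0.42) and Eomes (-0.40), named after their values were seen, also fell. Interferon response genes also fell, 4 of 22 with 18 not called (5 lower adjusted over the list alone; camera adjusted p 0.000519, median -0.12, adjusted p = 0.512 with an estimated correlation and 0.101 by fry). Mx1 differed by -0.60 ± 0.11 and Xaf1 by -0.49 ± 0.10, and neither was called without low dose replicate 1 (-0.61 and -0.43). The others were Oas1a (-0.45) and Usp18 (-0.19), named after their values were seen. Of 13 IL-2 and STAT5 genes, 3 fell and 10 were not called (5 lower adjusted over the list alone; camera adjusted p 0.00946, median -0.11, adjusted p = 0.512 with an estimated correlation). Socs1, a brake on cytokine signalling, differed by -0.25 ± 0.05 and Il2rb by -0.25 ± 0.05, and neither was called without low dose replicate 1 (-0.22 and -0.20). Socs3 (-0.23), the other member that fell, was named after its values were seen. Within 1 kb of the TSS Socs1 (-0.15) and Il2rb (-0.20) were not called, nor was the list (camera adjusted p 0.0534), which was also not called with the CD8 and NK score as a covariate (0.0675). With the B-cell score as a covariate none of Fcer2a (0.73), Cd79b (0.21), Gzmk (-1.01), Klrc1 (-1.16), Mx1 (-0.68), Xaf1 (-0.42), Socs1 (-0.21) and Il2rb (-0.14) was called, and the CD8 and NK, interferon and IL-2 lists were called (camera adjusted p 0.00225, 5.94e-05 and 0.0309).

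**Figure D4:**
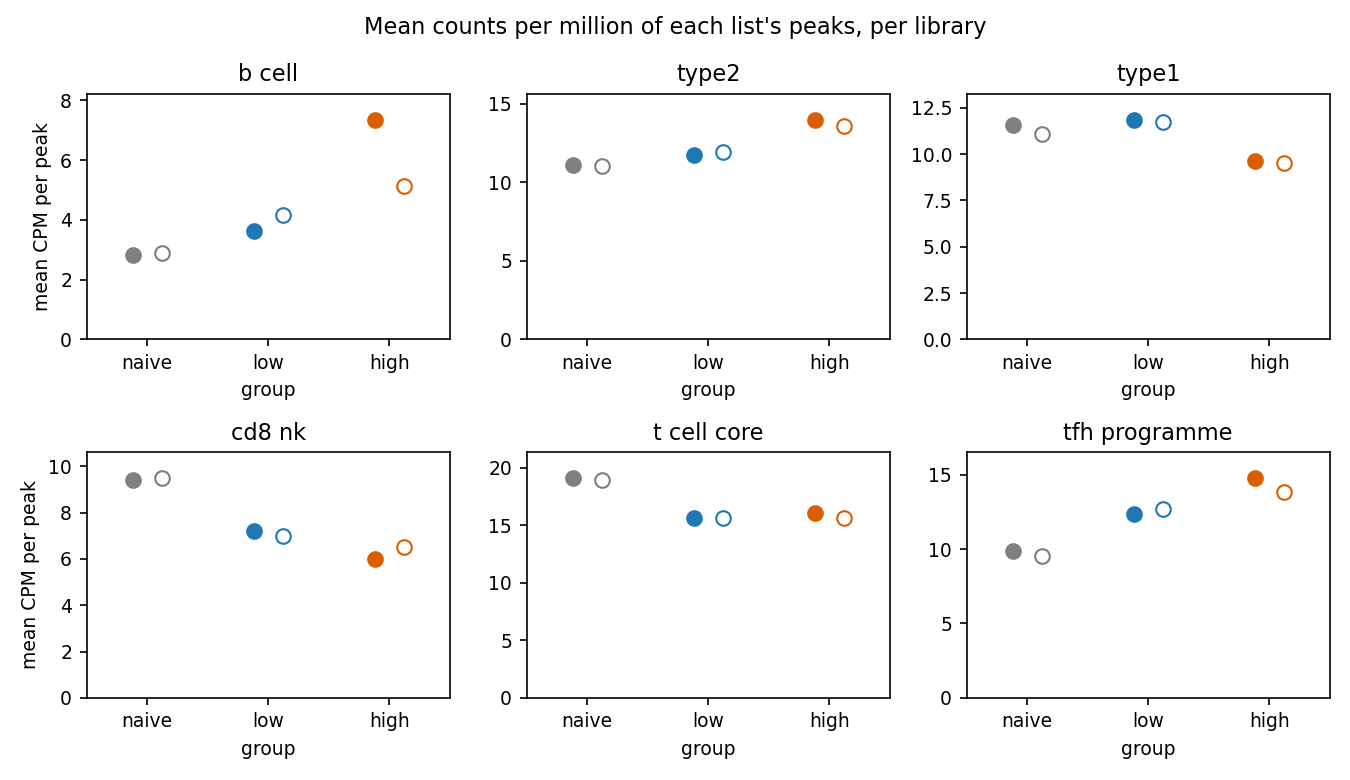
Mean CPM per peak of 6 lists (y axis) in each library, by group on the x axis; filled points are replicate 1 and open points replicate 2. The B-cell list stood at 7.35 and 5.12 in the high dose libraries against 3.63 and 4.17 in the low dose libraries.

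The remaining lists had camera adjusted p-values from 0.0707 to 0.948 between doses, and some were called under alternatives given here. With the B-cell score as a covariate the sort gate, naive and quiescence, type 17 and T cell receptor activation lists were called downward (medians -0.18, -0.09, -0.40 and -0.14), as they were with the CD8 and NK score as a covariate (-0.22, -0.14, -0.46 and -0.17). Of 9 sort gate genes, 2 rose, 2 fell and 5 were not called (2 and 2 adjusted over the list alone; camera adjusted p 0.530), and these genes were used to sort the cells. Selplg differed by -0.53 ± 0.05 with 4 of 4 peaks lower, and Ly6c2 by -0.51 ± 0.10. Pdcd1 rose by 0.41 ± 0.07 and Ly6c1 by 0.58 ± 0.15, and neither was called without low dose replicate 1 (0.39 and 0.53). Ly6c1 was also not called without high dose replicate 2 (0.45), low dose replicate 2 (0.63) or either naive library (0.57). With the B-cell score as a covariate Pdcd1 (0.14), Ly6c1 (0.82) and Selplg (-0.56) were not called. Pdcd1 was not called within 1 kb (0.20) or 10 kb (0.26) of its TSS. Ly6c1 was not called with nearest RefSeq genes (0.23) or with the naive libraries left out of the fit. Cd4 (-0.02), Cd44 (0.05), Cxcr5 (-0.05) and Foxp3 (-0.14) were not called, as was Tcf7 (-0.01), and Cxcr5 was called at -0.27 without high dose replicate 1. Their peaks of smallest p gave log2 differences between doses of 2.22 ± 0.33 at Cxcr5 (chromosome 9, 44575032 to 44575406), 2.02 ± 0.21 at Pdcd1 (chromosome 1, 94074693 to 94075260) and -1.003 ± 0.15 at Selplg (chromosome 5, 113828562 to 113828991). At the peaks given above for Tfh against naive cells, Cd4 differed by -1.19 ± 0.38, Ly6c1 by 0.57 ± 0.17 and Ly6c2 by -0.66 ± 0.12, and Cd44 was not called (0.45, adjusted p 0.0840). The Foxp3 peak (X chromosome, 7586137 to 7587066) was not called (-0.14), and the Tcf7 peak of smallest p (chromosome 11, 52313684 to 52314874) was higher by 0.27 ± 0.06. Of 16 Tcf7 peaks, 1 was higher and 3 were lower.

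Of 24 naive and quiescence genes, 1 rose and 4 fell between doses (1 and 4 adjusted over the list alone; camera adjusted p 0.138, and 0.00343 without high dose replicate 1), with Pdlim1 at -0.54 ± 0.06 (-0.21 and not called within 10 kb of its TSS) and Klf2, a factor of lymphocyte egress, at -0.41 ± 0.06 (-0.51 and not called with the covariate). Of 13 type 17 genes, 1 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p 0.119), with Il1r1 at 0.86 ± 0.12 and the IL-23 receptor Il23r at -1.17 ± 0.18. With the covariate neither was called (0.49 and -1.23), and Il1r1 was not called within 1 kb of its TSS (0.11) or with nearest RefSeq genes (0.53), where the list was called (camera adjusted p 0.0300). Of 13 regulatory T cell genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p 0.948, tested downward with a mean of 0.07 and a median of 0.01), and Lrrc32 rose by 0.97 ± 0.15 and was not called without low dose replicate 1 (0.94) or with the covariate (0.36).

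Of 20 T cell receptor activation genes, 1 rose and 5 fell between doses (2 and 6 adjusted over the list alone; camera adjusted p 0.0707), with Myc at -0.29 ± 0.05. The list was called downward without high dose replicate 1 (median -0.11, camera adjusted p 0.00138), without low dose replicate 2 (-0.06, 0.0321), and with library totals, loess offsets or a replicate block (0.0359, 0.0248 and 0.0483). Of 15 migration genes, 5 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p 0.307). Cx3cr1 rose by 0.47 ± 0.07, Gpr183, a guidance receptor of lymphoid follicles, by 0.36 ± 0.06, and Ccr2 differed by -0.57 ± 0.10 (0.07 over peaks within 10 kb). Cx3cr1 was not called within 1 kb of its TSS (0.22). Without high dose replicate 2 the migration list was called upward (median 0.14, camera adjusted p 0.0264), and the cell cycle and housekeeping lists downward (-0.13 and -0.08, 0.0264 and 0.0305). Of 17 cell cycle genes, 0 were called by edgeR, 3 had an unadjusted p below 0.05 and DESeq2 called 0 (camera adjusted p 0.110). Of 14 T cell core genes, 2 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p 0.836), with the kinase gene Zap70 at 0.34 ± 0.06 and the receptor gene Cd6 at -0.32 ± 0.05. Zap70 was not called with nearest RefSeq genes (0.15) or within 10 kb of its TSS (0.27), nor Cd6 within 1 kb (-0.11). Of 18 housekeeping genes, 1 fell and 17 were not called (0 called by edgeR adjusted over the list alone, 1 at an unadjusted p below 0.05 and 0 by DESeq2; camera adjusted p 0.307). That gene, the cyclophilin gene Ppia, differed by -0.17 ± 0.05 and was not called without high dose replicate 1 (-0.13), low dose replicate 1 (-0.15), low dose replicate 2 (-0.18) or either naive library (-0.18). Of 15 myeloid and dendritic genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p 0.364), with the dendritic integrin Itgax at -0.77 ± 0.09 (-0.16 and not called with nearest RefSeq genes) and Zbtb46 at -0.81 ± 0.10 (-0.40 and called with nearest RefSeq genes, -0.91 and not called with the covariate). Of 11 stromal and epithelial genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone; camera adjusted p 0.368), with Vim, vimentin, at -0.45 ± 0.05. Of 6 erythroid genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone; camera adjusted p 0.364, tested downward with a median of -0.12 and a mean of 0.08; 0.0306 by fry). With the covariate Myc (-0.30), Cx3cr1 (0.26), Gpr183 (0.21), Ccr2 (-0.69), Zap70 (0.39), Cd6 (-0.31), Ppia (-0.05) and Vim (-0.46) were not called.

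Among single peaks, a region at -40126 bp from the TSS of Maf (chromosome 8, 115747470 to 115748371) rose at high dose by 2.89 ± 0.21, from 1.80 ± 0.361 to 13.4 ± 1.43 CPM. An intronic peak of Vdr, the vitamin D receptor (chromosome 15, 97892015 to 97893212), rose by 2.42 ± 0.18 and a peak at -4101 bp from the TSS of Xbp1, a factor of the unfolded protein response (chromosome 11, 5517432 to 5517693), by 3.44 ± 0.26. Peaks assigned to Smtn, Gtf3c3 and Tsg101 were higher by 2.71, 1.68 and 1.90. The Xbp1 peak was at 4.93 CPM in naive cells, 0.544 at low dose and 5.89 at high dose, and the Gtf3c3 peak at 52.1, 7.27 and 23.2. Both were thus lower at low dose than in naive cells. At the Maf, Vdr, Smtn and Tsg101 peaks naive cells stood below low dose cells. A peak at -5428 bp from the TSS of Ifng (chromosome 10, 118435195 to 118436043) was at 0.183 ± 0.0476 CPM in naive cells, 20.7 ± 0.433 at low dose and 5.03 ± 0.539 at high dose. An intronic peak assigned to Il12rb2 (chromosome 6, 67375274 to 67376507) differed by -1.97 ± 0.13. Peaks assigned to Zscan12, Gnptab, P2rx4 and Dock9 differed by -2.44, -2.70, -1.61 and -2.43. These 12 peaks had adjusted p-values from 6.29e-07 to 1.98e-06 and kept their calls under every alternative run for them.

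Each dose was also set against naive cells. Low dose Tfh cells had 26619 peaks higher and 27042 lower, and high dose Tfh cells 27761 higher and 26250 lower. The doses shared 22728 higher peaks, against 8970.5 if the calls were independent, and 23168 lower peaks, against 8617. Both comparisons use the same naive libraries, which can add to the overlap. With naive replicate 1 as the control of low dose alone and naive replicate 2 as that of high dose alone, the doses shared 18141 higher and 19278 lower peaks, against 6352.5 and 6495 if the calls were independent. The correlation across peaks was then 0.888, against a mean of 0.00588 in the simulated draws. With the controls swapped the shared peaks were 18236 and 19436 and the correlation 0.891. With shared controls the correlation of the log2 differences across peaks was 0.936, against a mean of 0.487 in 5 simulated draws with no difference between groups. The simulated draws had a mean of 0.2 peaks called in both. Their covariance was 0.0385 against 3.32 observed. Peaks are not independent replicates.

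The dose difference and the Tfh difference were weakly related across peaks (Pearson 0.237, Spearman 0.17951, over 82378 peaks, which are not independent replicates). Of the peaks higher at high dose, 61.0% (6599) were higher in Tfh than in naive cells and 24.1% (2611) lower. Of the peaks lower at high dose, 42.7% were higher in Tfh cells and 42.7% lower. The Pearson value was 0.136 without high dose replicate 1 and 0.152 without low dose replicate 2.

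Promoters were unevenly represented among the called peaks (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted). They made up 15.7% of tested peaks, 18.6% of peaks higher in Tfh cells (adjusted p 3.1e-61) and 7.59% of peaks lower in Tfh cells (odds ratio 0.328). Between doses they made up 6.38% of higher peaks (adjusted p 1.1e-215) and 9.67% of lower peaks (adjusted p 2.2e-47). Introns held 43.5% of tested peaks, 51.2% of peaks higher at high dose and 48.8% of peaks lower in Tfh cells. These tests count peaks as independent, which they are not. Promoter peaks held 43.3% and 43.6% of the counts in naive, 48.6% and 48.3% in low dose and 45.9% and 48.3% in high dose libraries. Such shifts of whole libraries were not parted from the shares of called peaks.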

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

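The tests of B-cell carry-over, of a lower CD4 share and of the Il4 and Il13 excess ratios, the excess ratios of the lists, the test of CD8 and NK cells, and the settings with a B-cell or a CD8 and NK covariate or thinned libraries were chosen only after the result was seen.

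Between low and high dose, 205 peaks stood on opposite sides of naive cells, called in each dose and called as different between doses. Of these, 92 were above naive cells at low dose and below them at high dose. At gene level, 66 genes stood on opposite sides of naive cells in the same way. Fcer2a differed from naive cells by -1.03 at low dose and 0.57 at high dose (adjusted p of the dose difference 0.00246, edgeR). Il18rap, an IL-18 receptor chain, differed by 0.59 and -0.60 (0.00183), and Cd6 by 0.14 and -0.18 (0.00394). Fcer2a is itself a B-cell gene. With the B-cell score as a covariate none of these genes was called between doses: Fcer2a went from 1.60 ± 0.23 to 0.73 ± 0.31 (log2 difference ± SE, adjusted p 0.449), Il18rap from -1.18 ± 0.16 to -0.76 ± 0.29 (0.369) and Cd6 from -0.32 ± 0.05 to -0.31 ± 0.11 (0.302).

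B-cell marker chromatin was higher at high dose, with a list mean of 7.35 and 5.12 CPM per peak against 3.63 and 4.17 at low dose, in cells sorted on CD4 and PD-1. The mesenteric lymph node holds B cells, in which all 16 list genes are active. If cells of every other type had replaced CD4 cells, the myeloid, CD8 and NK, stromal and erythroid lists would all rise at high dose. Their medians of edgeR fitted values were 0.16, -0.44 (quartiles -0.67 to -0.34), -0.05 and -0.12, so the rise was not shared by all these lists. The CD8 and NK list fell beside the type 1 list and was not parted from it, so its fall cannot exclude a loss of CD4 cells. B cells carried through the sort and another difference of high dose replicate 1 cannot be told apart: 100% of the list genes stood higher in that library than in replicate 2, as did 80.9% of 2359 other genes called higher at high dose and all 15 called Tfh programme genes. The 2359 genes leave out only the list itself and still hold B-cell genes such as Blnk, so their share cannot part the causes. Their excess over low dose in replicate 1 relative to replicate 2 had a median of 1.52, against 3.05 in the called B-cell genes. Not every B-cell gene was called higher at high dose: 12 were and 4 were not, Pax5 among these. Adjusted over the list alone, 1 B-cell gene was lower. With the CD8 and NK score as a covariate the B-cell list was at -0.21 and not called (adjusted p 0.142). That fit rests on small gaps between replicates, chiefly at high dose. A difference between Tfh cells of the infection doses stays open and untested.

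Type 2 genes were higher and type 1 genes lower at high dose, and B cells in the high dose libraries could have moved both. With the B-cell score as a covariate the type 2 median was 0.17 against 0.22 without it, and the type 1 median -0.35 against -0.33. Both lists were called in that fit (camera adjusted p 0.0206 and 4.81e-12). The score also followed the groups, at 2.88 and 2.36 at high dose and 1.86 and 2.06 at low dose (log2). The fit therefore rests on gaps between replicates and cannot by itself exclude B cells as the cause. The type 2 list was not called within 1 kb of the TSS (0.0534). Single calls ended: Il4 went from 2.04 ± 0.20 to 1.72 ± 0.39 and Tbx21 from -1.14 ± 0.10 to -1.09 ± 0.20 (log2 difference ± SE), mostly through the wider error. The excess over low dose in replicate 1 relative to replicate 2 had a median of 3.05 over the 12 of 16 B-cell genes called higher (quartiles 2.66 to 3.55). It was 1.07 over the 10 of 19 type 2 genes called higher (0.905 to 1.49) and 0.942 over the 13 of 24 type 1 genes called lower (0.815 to 0.990). From the mean CPM of all members the ratios were 2.83, 1.21 and 0.937. The type 2 and type 1 ratios lay below the B-cell ratio, which argues against B cells as the whole cause of either list's change. These ratios rest on 2 high dose libraries. The higher of the Il4 and Il13 ratios was 1.07, also below the B-cell quartiles. Among the type 2 genes called higher, Il4, Il13, Rad50 and Kif3a share a locus, so their ratios are not independent. Bhlhe41 (2.998) and Il24 (2.12), singled out after their values were seen, lay within the B-cell range of 1.88 to 3.90 and were at 0.0051 and 0.28 with the covariate, so for these type 2 genes B cells stay open. The 15 called Tfh programme genes had a median of 1.66. CD8 and NK cells in the low dose libraries stay open for the type 1 change, since their markers fell too. The median of these markers was -0.44 in edgeR fitted values, although the Tfh cells were sorted on CD4, PD-1 and CXCR5. Not every marker fell: Cd8a (-0.29, adjusted p 0.308) and Klrb1c (0.0057) were not called, nor was Ncr1 with nearest RefSeq genes (-0.013), beside -1.14 for Tbx21. These markers were singled out after their values were seen. With their score as a covariate the type 1 median was -0.38, but that fit left their own list called at -0.30, and their ratios overlapped those of type 1 genes (quartiles 0.980 to 1.11). The type 2 list was not called in that fit (0.08, adjusted p 0.0556). A difference between Tfh cells of the acute and chronic infection stays open as a hypothesis, untested beyond these 2 libraries per group.

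Of the called peaks, 63.0% were higher at high dose, and depth, scaling and B cells could each have tilted the share. Depth is argued against by thinning every library to the smallest total, with 62.8%. With loess offsets the share was 52.8%, so abundance-dependent scaling may account for it. With the B-cell score as a covariate it was 50.8% of 236 peaks (95% exact Clopper-Pearson interval 44.3 to 57.4), so B cells may account for it too, although this covariate absorbs any other difference of high dose replicate 1. The median size of the log2 difference over the peaks called without it went from 1.03 to 0.64 and the median standard error from 0.233 to 0.402, with 93.2% of signs kept, so calls ended through both, and the dose itself stays open.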

How the results depend on the processing

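The settings with a B-cell or a CD8 and NK covariate, thinned libraries, nearest RefSeq genes and split naive libraries were chosen only after the result was seen. Leaving out each library in turn assumes that a lone library varies like the other groups. It gave 48723 to 56998 peaks for the Tfh difference and 7303 to 16679 for the dose difference, 45063 to 55012 for low dose and 46510 to 54744 for high dose against naive cells. It gave 12205 to 15016 genes for the Tfh difference and 1060 to 4144 for the dose difference, a Pearson alignment of 0.136 to 0.320, and 6 to 6 and 7 to 10 called lists. The lowest dose counts, 7303 peaks and 1060 genes, came without low dose replicate 1, and without high dose replicate 1 they were 7582 and 2022. The lowest alignment came without high dose replicate 1, and it was 0.152 without low dose replicate 2. Of 57 called genes named for the dose difference, 44 kept the call without high dose replicate 1 and 29 without low dose replicate 1. Of 81 named for the Tfh difference, all kept it without any Tfh library and 80 without either naive library, where Psmb4 lost it (0.25 and 0.25).

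For the dose difference DESeq2 called 10941 peaks (6492 higher, 4449 lower). Against a fold of 1.5, 4909 dose peaks, 35716 low dose peaks, 6675 Tfh genes and 274 dose genes were called, since that test asks for more than a difference. With the B-cell covariate the counts were 30971 Tfh peaks, 236 dose peaks, 18274 high dose peaks, 8619 Tfh genes and 66 dose genes, and Egr3 reversed between doses (-0.0027). Of the 57 named dose genes 8 kept the call, and of the 81 named for the Tfh difference 71 did. By construction it also took the B-cell list to -0.0083. With the CD8 and NK score as a covariate the B-cell list reversed in both comparisons (-1.49 and -0.21), in a fit that parts the score poorly from the groups. Peaks within 1 kb, a smaller set of peaks, gave 7032 Tfh and 1152 dose genes, and nearest RefSeq genes gave 9844 and 2262. The estimated correlation called 0 and 0 lists (edgeR and limma; 1 and 2 at unadjusted p below 0.05, 13 and 5 by fry).

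Reversed in the Tfh difference within 1 kb were Il21r (0.046), Stat5b (0.15), Gpr15 (-1.0015), Ccnb1 (0.074), Snrpd3 (0.057), Cd44 (0.49) and the sort gate median (0.49, adjusted p 0.326). Within 10 kb these were Stat5b (0.043), Ccnb1 (0.042) and Snrpd3 (0.087), and for the dose difference Ccr2 (0.069). With nearest RefSeq genes these were Igf1r (-0.57), Stat4 (0.15), Top2a (-0.054), Ccnb1 (0.064), Cd44 (0.17) and Bcl6 (-0.16). Called on the reversed side were Stat5b, Gpr15 and Cd44 within 1 kb, and Igf1r, Stat4 and Bcl6 with nearest RefSeq genes. For all these changes the cause was not tested, save where construction is named. The type 2 and IL-2 lists lost their dose calls within 1 kb (adjusted p 0.0534 each) and with the CD8 and NK covariate (0.0556 and 0.0675). The Tfh programme list lost its dose call with the B-cell covariate (median 0.12, adjusted p 0.207) and with the CD8 and NK covariate.

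A block on the replicate number gave 57039 Tfh and 16950 dose peaks. The replicate numbers did not pair libraries, since deviations correlated at -0.044, -0.013 and -0.075 between groups. Counts under RLE factors, library totals, loess offsets, other filters, autosomes, the groups compared alone and thinning stayed within 1.5 times of those reported. The overlap was 37897 peaks at an adjusted p below 0.01 and 40286 with DESeq2, against 45896, and with a separate naive library for each dose 37419 and 37672. GC offsets, the block with GC offsets, and the motif settings were not run. Small changes were often missed in simulation at this depth and with 2 libraries per group: 18% of 1.5-fold dose differences in peaks were recovered. Only 200 peaks were changed there, against 17163 called here. Benjamini-Hochberg adjustment is stricter when fewer peaks change, so recovery in these data may be higher. Thinning gave 16335 dose peaks against 17163, so a loss of depth of that size changed few calls, and depth was not parted from the number of libraries.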

Other observations

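The tests of how many genes had most of their peaks changed to the same side were chosen only after the result was seen.

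Among 2882 protein-coding genes with at least 5 peaks, 22 had at least 80% of their peaks higher at high dose and 10 had at least 80% lower. The higher genes included Rasgrp3, a Ras activator, with 7 of 7 peaks (gene-level log2 difference 1.91), Blnk, an adaptor of the B-cell receptor, with 8 of 8 (1.55), and Tnfrsf13b, a BAFF and APRIL receptor, with 5 of 6 (1.09). Smco4 had 19 of 21 peaks higher (0.71) and Fcrl1 8 of 10 (1.04). Over these 22 genes the excess over low dose in high dose replicate 1 relative to replicate 2 had a median of 2.07 (quartiles 1.54 to 2.80), and 1 of them, H2-Aa, was in the B-cell list. That list is short and lacks Blnk, so this count does not measure how many of the 22 are active in B cells. The counts of 22 and 10 were not repeated without high dose replicate 1.

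The lower genes included Il12rb2 with 8 of 8 peaks (-0.94), Esm1 with 9 of 10 (-0.99), Il1rl1 with 6 of 7 (-1.84), Gpr146 with 6 of 6 (-0.55) and Cxcr3 with 4 of 5 (-1.06). In Tfh against naive cells, 344 genes had at least 3 peaks called higher and at least 3 called lower.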
